A study of Mus musculus with 5 samples.

How the data were processed

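Sorted mouse CD8 T cells were profiled by RNA sequencing in 5 libraries, 3 labelled PHD2-deltaT and 2 labelled WT. Per the labels' protocols, RNA was extracted with the RNeasy Plus Mini kit, libraries were made with the Ovation SoLo RNA-Seq System and sequencing was paired-end. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.3, HTSeq 0.9.1 and the mm10 build were used. How counts were scaled, which tool made the authors' comparison and whether counting used strand are not given in the sources used here.

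The authors deposited a table of 11564 genes with a normalized signal (called normalized counts per the file headers) for each library. The authors also deposited log2 values, namely log2 mean expression and log2 fold changes, and adjusted p-values headed FDR, blank for 225 genes. From the library columns, the sign of the deposited log2 fold change is WT over PHD2-deltaT. The selection deposited by the authors held the 151 genes with an FDR under 0.05 and a log2 fold change above 0.5 in size.

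The deposited signal values were examined before a test was chosen. In each library every value was a whole multiple of a single step (tolerance 1e-06), and the whole numbers summed to between 19982939 and 19985825. They left gaps as reads multiplied by a constant and rounded up would. Constants of 1.30, 1.35 and 1.55 in PHD2-deltaT and 1.85 and 1.36 in WT accounted for 99.6% to 99.7% of values, against 54.1% to 77.0% by chance. Dividing by them gave 15382182, 14838901 and 12925630 inferred reads in PHD2-deltaT and 10818533 and 14710034 in WT. These depths are inferences from the values. Every gene had at least 1 inferred read in every library, the lowest row mean was 4.37, and genes below that were not analysed here.

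Spreadsheet damage had turned 17 gene names into date serials, and these were named again from their gene IDs. Of the 11564 IDs, 11538 were found in the reference names. Gene positions, exon lengths, GC content and exon overlaps came from GENCODE M21 on GRCm38 (mm10). Of 141 genes that the naming rule took, 50 share exon bases with another gene and 6 share over 20%.

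Genes with a value of at least 10 in at least 2 libraries were kept (11534). Log2(value + 1) was fitted in limma 3.58.1 (R 4.3.3) with genotype as the only term, all 5 libraries and eBayes with a mean-variance trend (limma-trend). Fold changes are on this scale, which understates the change of low genes. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. There were 3 residual and 12.8 prior degrees of freedom. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Adjustment was over 19 biological lists and separately over 13 testable other lists. Estimated correlations ran from -0.178 (myeloid markers) to 0.950 (mitochondrially encoded genes). For lists whose estimate exceeds the preset, camera p-values at the preset are too small. The estimated setting also raised the unadjusted camera p of lists whose estimate lay under the preset. For autophagy and mitophagy genes (-0.023) it went from 0.00994 to 0.0685, and for natural killer markers (-0.006) from 0.00502 to 0.0638. Calls lost under that setting therefore do not measure correlation alone. Tables and figures used Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

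The gene lists, the threshold, the naming rule and most of the other settings (pseudocounts, filters, TMM and quantile scaling, limma without the trend, robust eBayes, array weights, each library left out) were fixed before the data were examined. The rule named the PHD and HIF pathway genes and the 12 largest changes in each direction among called genes with separated values and a mean of at least 50. It left out predicted genes, of which 13 higher and 10 lower were called. It also named up to 4 members of each list and up to 10 of the authors' selected genes, by smallest p. A gene that the rule took is not reported here. Genes named outside this rule (H2-Aa, H2-Eb1, Ighd, Ighm, Dusp4, Spry1, Dusp5, Pgm2, Gys1, Gbe1, Ppp1r3b and the neighbours of Egln1) were chosen after their values were seen.

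The test was run on simulated data with known changes, drawn from the means and inferred depths of these libraries with 200 changed genes in each of 5 simulations. A further set of genes was raised 1.25-fold in each simulation. Those genes enter the number of calls but not the shares recovered. Pooled over the 5 simulations, the first of which tested 11529 genes, limma-trend recovered 18.1% of 1.25-fold, 72.4% of 1.5-fold, 92.3% of 2-fold and 98.0% of 4-fold changes. Of its calls, 3.57% were false. Every simulated gene had the same dispersion (0.00557), so genes that vary around the mean-variance trend were not simulated. These shares may therefore not hold for the real genes. Replicate numbers in the text follow the order of the labels within each genotype, since the labels give none. Replicates were compared before averaging. The chi-square per gene was 4.63 between the WT libraries and 5.75 to 6.94 between PHD2-deltaT libraries, so none looked like the same library deposited again. Correlations across genes were 0.993 within groups and 0.988 to 0.990 between them. The first principal component held 45.5% of the variance and separated the genotypes.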

Results

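RNA was sequenced from sorted mouse CD8 T cells, the lymphocytes that kill infected and tumour cells. The design compared 3 libraries labelled PHD2-deltaT, by the name a PHD2 knockout, with 2 libraries labelled wild type (WT). PHD2, the product of Egln1, is an oxygen-dependent prolyl hydroxylase that marks the HIF transcription factors for degradation. The deposited table listed 11564 genes with normalized counts summing to between 19593220 and 20253007 per library, and the reads inferred behind them numbered 10818533 to 15382182. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

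The targeted gene was examined first in every library. Egln1 (ENSMUSG00000031987; mm10 chromosome 8, 124908587 to 124949324, minus strand, 5 exon blocks) was higher, not lower, in the libraries labelled PHD2-deltaT. Its normalized counts were 5447, 4327 and 4993 there, and 1927 and 2182 in WT. The group means were 4922 ± 563 (SD, n = 3) and 2054 ± 180 (SD, n = 2), a log2 fold change of 1.26 with a standard error of 0.09 (limma-trend, adjusted p = 2.86e-07). Gene-level counts cover all exons and cannot separate deleted exons from kept ones, so this value checks nothing about the deletion itself. Because the targeted gene went against the label, every direction given here is that of the libraries labelled PHD2-deltaT.

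Of 11534 genes tested, 461 passed an adjusted p of 0.05, 343 of them higher and 118 lower in the libraries labelled PHD2-deltaT. Most changes were modest, with a median of 1.53-fold among the higher calls and 1.41-fold among the lower ones. At least 2-fold changes numbered 89 higher and 11 lower. All 461 had PHD2-deltaT values entirely on one side of the WT values. Of all genes tested, 30.5% had such values, against 20% by chance for 3 libraries against 2. The count fell to 244 without WT replicate 2 (209 higher, 35 lower) and to 96 in limma without the mean-variance trend.

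**Figure D1:**
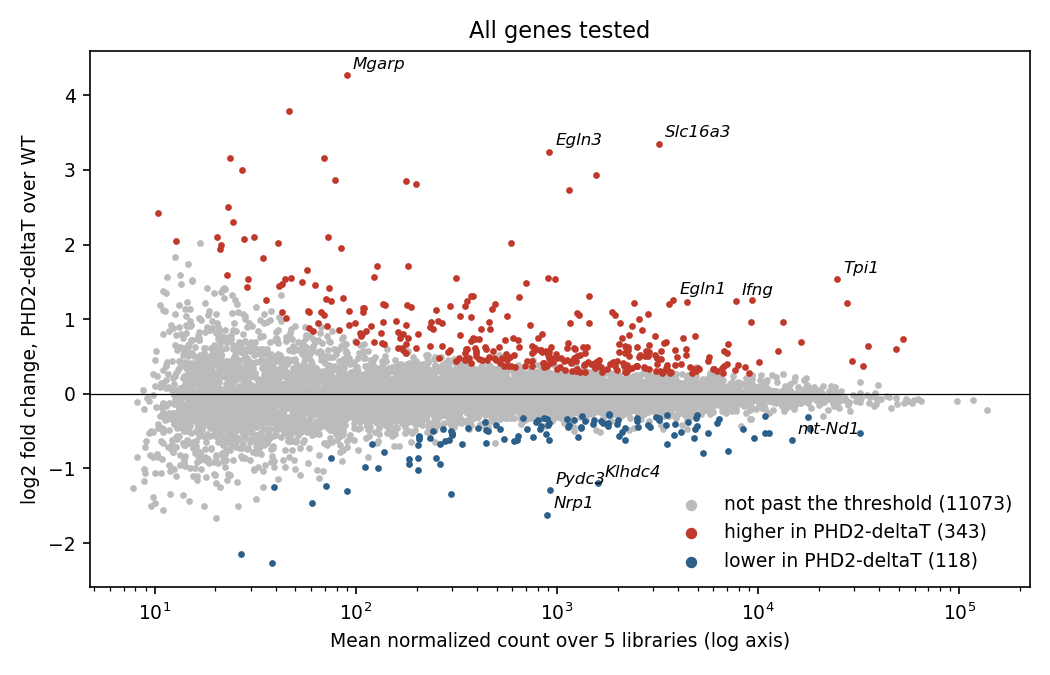
Log2 fold change (PHD2-deltaT over WT) against mean normalized count over 5 libraries on a log axis, 1 point per gene, for 11534 genes. The 343 genes higher in the libraries labelled PHD2-deltaT (red) reach larger changes than the 118 lower ones (blue).

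Among called genes with a mean of at least 50 normalized counts, predicted genes left out, the 12 largest increases included several known hypoxia-inducible and metabolic genes. Mgarp, a mitochondrial transport protein, had a log2 fold change of 4.27 ± 0.42 (SE). The lactate exporter Slc16a3 rose from 501 ± 166 (SD, n = 2) to 5010 ± 613 (SD, n = 3), a log2 fold change of 3.35. Egln3, the inducible sister enzyme of PHD2 (mm10 chromosome 12, 54178981 to 54203860), rose from 147 ± 9.64 to 1429 ± 344, by 3.25 on the log2 scale. Itga7 (3.16), Ak4 (2.94), H2-Ab1 (2.87), Apbb1 (2.85), Aldoc (2.80), Bnip3 (2.73), Plcxd1 (2.10), Vegfa (2.02) and Adam8 (1.96) completed the 12. All 12 passed in each fit that left out 1 library, but Mgarp (adjusted p = 0.061), Itga7 (0.096), Aldoc (0.075), Plcxd1 (0.14) and Adam8 (0.061) were not called by limma without the trend. Exons of Bnip3 and Plcxd1 overlap other genes over 22.3% and 29.3% of their bases, and those counts are less certain.

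Under the same conditions the 12 largest decreases were smaller. Nrp1, a semaphorin and VEGF co-receptor, went from 1507 ± 145 (SD, n = 2) in WT to 489 ± 12.03 (SD, n = 3), a log2 fold change of -1.62 ± 0.09 (SE, adjusted p = 1.66e-08). Fanca (-1.30), Pydc3 (-1.29), Syt6 (-1.23), Klhdc4 (-1.19), Serpine2 (-0.99), Nudt7 (-0.97), Snn (-0.94), Npas4 (-0.94), Gucy1a3 (-0.87), Trpm1 (-0.87) and the ERK-pathway inhibitor Spry2 (-0.86) followed. Pydc3 (adjusted p = 0.081) and Npas4 (0.055) were no longer called without WT replicate 2, and Serpine2 (0.21) and Trpm1 (0.069) without WT replicate 1. Pydc3 was also lost under robust eBayes (adjusted p = 0.45). Limma without the trend did not call Pydc3 (adjusted p = 0.32), Serpine2 (0.21), Snn (0.076), Npas4 (0.14) or Trpm1 (0.14). Nrp1, Fanca, Klhdc4 and Nudt7 lie on chromosome 8 at 3.50, 1.64, 3.12 and 10.8 Mb from Egln1.

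Glycolytic genes rose almost as a whole. Of 18 glycolysis genes tested, 17 were higher and 0 lower, all 18 when adjusted over the list alone, with a median log2 fold change of 0.85. Triose phosphate isomerase Tpi1 went from 11541 ± 888 to 33420 ± 249, a log2 fold change of 1.54. Pfkl (1.26), the glucose transporter Slc2a1 (1.23) and Eno1 (1.22) were also higher. Without the trend 12 of the list were called. The list passed camera with a preset correlation of 0.01 (adjusted p = 1.97e-49) and also with an estimated correlation (adjusted p = 0.034). It was the only 1 of the 19 biological lists to do so.

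Of 34 HIF target genes tested, 22 were higher and 0 lower, 27 when adjusted over the list alone, and the median log2 fold change was 0.63. Beside Egln3, Ak4 and Bnip3, the angiogenic factor Vegfa went from 208 ± 22.4 to 850 ± 139. The list had 9 calls without the trend. The camera adjusted p was 2.51e-40 with the preset correlation and 0.186 with an estimated correlation, and fry gave an adjusted p of 0.0397. Among the 8 tested genes of the PHD and HIF pathway, Egln1 and Egln3 rose. Values of the others did not pass, with log2 fold changes of 0.17 for Egln2, 0.03 for Hif1a, 0.58 for Epas1, 0.06 for Arnt, 0.07 for Vhl and -0.08 for Hif1an. The signs of Hif1a and Arnt turned without WT replicate 1 and without WT replicate 2, respectively. For this pathway list the camera adjusted p was 0.000135, and the adjusted p was 0.203 with an estimated correlation.

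**Figure D2:**
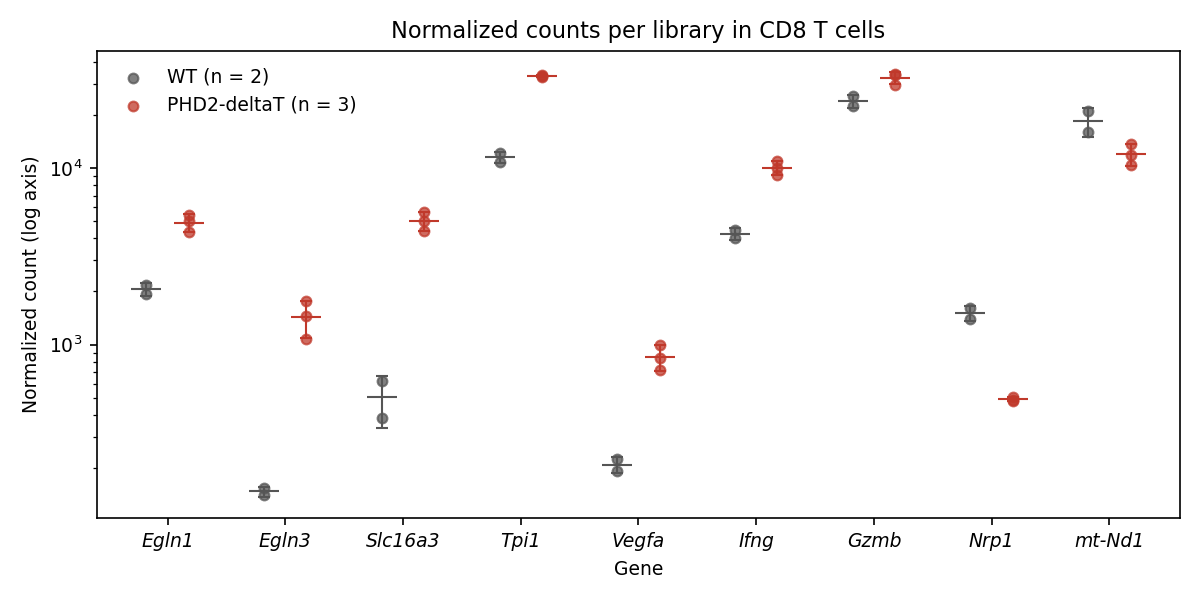
Normalized counts on a log axis for 9 genes in each library, with dots for libraries and a dash with a bar for the group mean and SD (PHD2-deltaT, n = 3; WT, n = 2). Egln1 lies between 4327 and 5447 in the libraries labelled PHD2-deltaT and at 1927 and 2182 in WT.

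Mitochondrial metabolism genes encoded in the nucleus showed no call. Of 20 tricarboxylic acid cycle genes and 34 nuclear oxidative phosphorylation genes, 0 passed, and 0 when adjusted over the list alone. Their median log2 fold changes were -0.03 and -0.00, and their camera adjusted p were 0.228 and 0.882. The members with the smallest p were Dld (-0.14) and Ogdh (-0.14) in the first list and Atp5d (0.14) and Ndufb8 (0.14) in the second. Without PHD2-deltaT replicate 2 the first list passed camera (adjusted p = 0.032). Of the 7 tested genes encoded in the mitochondrial genome, 6 were lower, all 7 when adjusted over the list alone. mt-Nd1 had a log2 fold change of -0.62 and mt-Co1 of -0.52, and the list's median was -0.52 (camera adjusted p = 4.78e-10; adjusted p = 0.203 with an estimated correlation). Mitochondrially encoded genes in the deposited table took 0.441%, 0.470% and 0.373% of the normalized counts in PHD2-deltaT and 0.540% and 0.698% in WT. Only 7 of the list's 13 genes were tested, so these shares may not give the whole mitochondrial RNA of a library. Without WT replicate 2, and in limma without the trend, 0 of the 7 passed. Under robust eBayes 2 of the 7 passed, and mt-Nd1 did not (adjusted p = 0.060).

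Of 19 cytotoxic effector genes, 6 were higher and 0 lower, 8 when adjusted over the list alone, with a median log2 fold change of 0.24. The interferon gamma gene Ifng rose most clearly, from 4242 ± 335 to 10062 ± 947 (log2 fold change 1.24, adjusted p = 1.11e-07), with 25.9% of its exon bases shared with a predicted gene. Granzyme B (Gzmb, 0.44), the chemokine Ccl3 (0.43) and Tnf (0.43) rose less. These last 3 were no longer called without WT replicate 2 (adjusted p = 0.19, 0.10 and 0.20), where 1 gene of the list passed. They were not called without the trend either (adjusted p = 0.19, 0.17 and 0.19), again with 1 gene of the list passing. The list's camera adjusted p was 8.68e-08, the adjusted p was 0.284 with an estimated correlation, and fry gave an adjusted p of 0.117.

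Of 20 effector differentiation genes, 9 were higher and 0 lower, and 11 were higher and 1 lower when adjusted over the list alone. The median log2 fold change was 0.30. Anxa2 (1.55), the T-box factor Tbx21 (0.79) and the nuclear receptor Rora (1.17) were higher in every fit without 1 library, and S100a6 (1.27) was not called without WT replicate 2 (adjusted p = 0.11). The count was 4 without PHD2-deltaT replicate 2, 4 higher and 1 lower without WT replicate 1, and 5 without WT replicate 2. It was 7 under quantile normalization and 2 without the trend, where Rora and S100a6 were not called (adjusted p = 0.16 and 0.16). The camera adjusted p was 2.55e-08 and 0.186 with an estimated correlation, and fry gave an adjusted p of 0.0397. Of 12 central memory genes, 4 rose, among them Ly6c2 (0.52), Eomes (0.51) and Ccl5 (0.43). Adjusted over the list alone, 5 were higher and 1 lower (median 0.26, camera adjusted p = 0.000357; adjusted p = 0.284 with an estimated correlation). Ccl5 was lost without WT replicate 2 (adjusted p = 0.36), where the list had 2 calls, and the list had 0 without the trend.

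Of 22 naive and memory genes, 1 was higher and 2 were lower, and 4 and 3 when adjusted over the list alone. Bach2, a repressor of effector differentiation, fell by 0.43 on the log2 scale, and the co-stimulatory receptor Cd28 by 0.47. Dapl1 was higher by 0.33, a call lost in 4 of the 5 fits without 1 library. Cd28 was lost without WT replicate 2 (adjusted p = 0.21), and without the trend the list had 0 calls. Of 17 inhibitory receptor and exhaustion genes, 3 were higher and 1 lower, and 4 and 4 when adjusted over the list alone. Bhlhe40 (1.10), which other work describes as a hypoxia-responsive repressor, was higher in every fit without 1 library. Nr4a3 (0.34), Havcr2 (1.10) and Cd200 (-0.37) were each lost without WT replicate 2 (adjusted p = 0.14, 0.15 and 0.093), where 1 gene of the list was called, and 2 without WT replicate 1. Havcr2 (adjusted p = 0.052) and Cd200 (0.070) were also lost without WT replicate 1, and Havcr2 without PHD2-deltaT replicate 1 (0.096). Without the trend only Bhlhe40 of this list was called. Neither list passed camera (adjusted p = 0.873 and 0.834). The inhibitory list had a median log2 fold change of -0.02, a mean of 0.16 and an upward test direction.

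Of 30 interferon response genes tested, 16 were higher and 0 lower, 26 when adjusted over the list alone, and the median log2 fold change was 0.44. The ubiquitin-like protein Isg15 went from 195 ± 18.3 to 467 ± 53.9. Its protease Usp18 (1.18), Irf7 (0.80) and Oasl2 (1.31) were also higher. Without WT replicate 1, 9 passed, and 4 passed without the trend, where Irf7 (adjusted p = 0.072) and Oasl2 (0.10) did not. The camera adjusted p was 3.63e-25 and 0.186 with an estimated correlation, and fry gave an adjusted p of 0.0397. Of 28 cytokine signalling genes, 9 were higher and 0 lower, 14 when adjusted over the list alone (median 0.22). They included the STAT5 target Cish (1.08), Jak3 (0.65), Pim1 (0.58) and Socs3 (0.63), of which Cish alone was called without the trend. The camera adjusted p was 2.17e-10 and 0.186 with an estimated correlation, and fry gave an adjusted p of 0.0397.

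Of 23 T cell receptor activation genes, 5 were higher and 0 lower, 9 when adjusted over the list alone (median 0.16). Irf8 (0.54), Tnfaip3 (0.50) and Nfkbid (0.49) were called in every fit without 1 library, but not by limma without the trend (adjusted p = 0.096, 0.092 and 0.093), where this list and the next had 0 calls. Irf8 lies on chromosome 8, 4.18 Mb from Egln1. Batf3, at 30.3 ± 11.7 against 7.46 ± 4.86, was lost in 3 of these fits. Without WT replicate 1 and without PHD2-deltaT replicate 3 the list had 3 calls each. Of 22 immediate early and stress genes, 6 were higher and 0 lower, 7 when adjusted over the list alone (median 0.22), among them Ier3 (1.12), Atf3 (0.70), Junb (0.49) and Ppp1r15a (0.48). Without WT replicate 2, 3 passed, and Junb (adjusted p = 0.059) and Ppp1r15a (0.087) did not. The camera adjusted p were 1.71e-05 and 2.35e-07, and the adjusted p were 0.267 and 0.186 with an estimated correlation. Of 22 integrated stress and unfolded protein response genes, 3 were higher: Trib3 (0.96), Asns (0.58) and Sesn2 (0.55). The count was also 3 when adjusted over the list alone (median 0.06, camera adjusted p = 0.00373; adjusted p = 0.387 with an estimated correlation). Sesn2 was lost without WT replicate 2 (adjusted p = 0.20) and PHD2-deltaT replicate 3 (0.061), and the list's call without WT replicate 2 (0.058) and PHD2-deltaT replicate 2 (0.054). Trib3 alone was called without the trend.

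Among the remaining lists, 4 of 20 homing and adhesion genes were higher and 1 lower, and 5 and 2 when adjusted over the list alone. Vim (0.95) and Cxcr4 (0.47) were higher and the integrin Itgae fell by 0.63. Cxcr4 and Itgae were lost without WT replicate 2 (adjusted p = 0.069 and 0.053), and Cxcr4 without WT replicate 1 (0.10). The list had 1 call without WT replicate 2, 3 without WT replicate 1 and 0 without the trend. The list's camera adjusted p was 0.037, lost without WT replicate 2 (0.26) and PHD2-deltaT replicate 3 (0.29), and the adjusted p was 0.415 with an estimated correlation. Of 18 autophagy and mitophagy genes, the mitophagy receptors Bnip3 (2.73) and Bnip3l (0.85) rose, 2 also when adjusted over the list alone. Bnip3l was not called without the trend (adjusted p = 0.13). Bnip3 and Bnip3l are also on the HIF target list, and the autophagy and mitophagy list was not tested without them. The median was 0.03 (camera adjusted p = 0.0157, or 0.186 with an estimated correlation, and fry adjusted p = 0.0397). Of 25 apoptosis genes, Bcl2l1 was higher by 0.40 and Bcl2l11, which encodes the pro-apoptotic BIM, fell by 0.38, and both calls were made adjusted over the list alone. Bcl2l1 was lost without WT replicate 2 (adjusted p = 0.15), both were lost without the trend, and the camera adjusted p was 0.239. Of 21 cholesterol synthesis genes, 0 passed, and 0 when adjusted over the list alone, although the list passed camera downward (median -0.09, adjusted p = 0.0065; adjusted p = 0.387 with an estimated correlation). That call was lost without WT replicate 2 (adjusted p = 0.10). Msmo1 (-0.23) and Hmgcs1 (-0.19) had its smallest p. Of 34 cell cycle genes, 0 passed, and 0 when adjusted over the list alone (median -0.02, camera adjusted p = 0.228). Mki67, at 216 ± 53.5 against 296 ± 6.16, and the list itself passed without PHD2-deltaT replicate 3 (adjusted p = 0.041 and 0.0072). Across all genes, limma-trend gave an unadjusted p under 0.05 for 1731.

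The medians of several lists that passed camera moved over 1.5-fold when 1 library was left out. Without WT replicate 2 they fell to 0.15 for cytotoxic effector, 0.14 for central memory, 0.12 for immediate early and stress, and 0.03 for integrated stress genes, the last also without PHD2-deltaT replicate 2 (0.03). The homing and adhesion median ranged from 0.03 to 0.13. The autophagy and mitophagy median was 0.07 without WT replicate 2, 0.06 without WT replicate 1 and 0.06 without PHD2-deltaT replicate 3. The cholesterol synthesis median was -0.03 without PHD2-deltaT replicate 1, and that of the PHD and HIF pathway 0.20 without WT replicate 1.

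**Figure D3:**
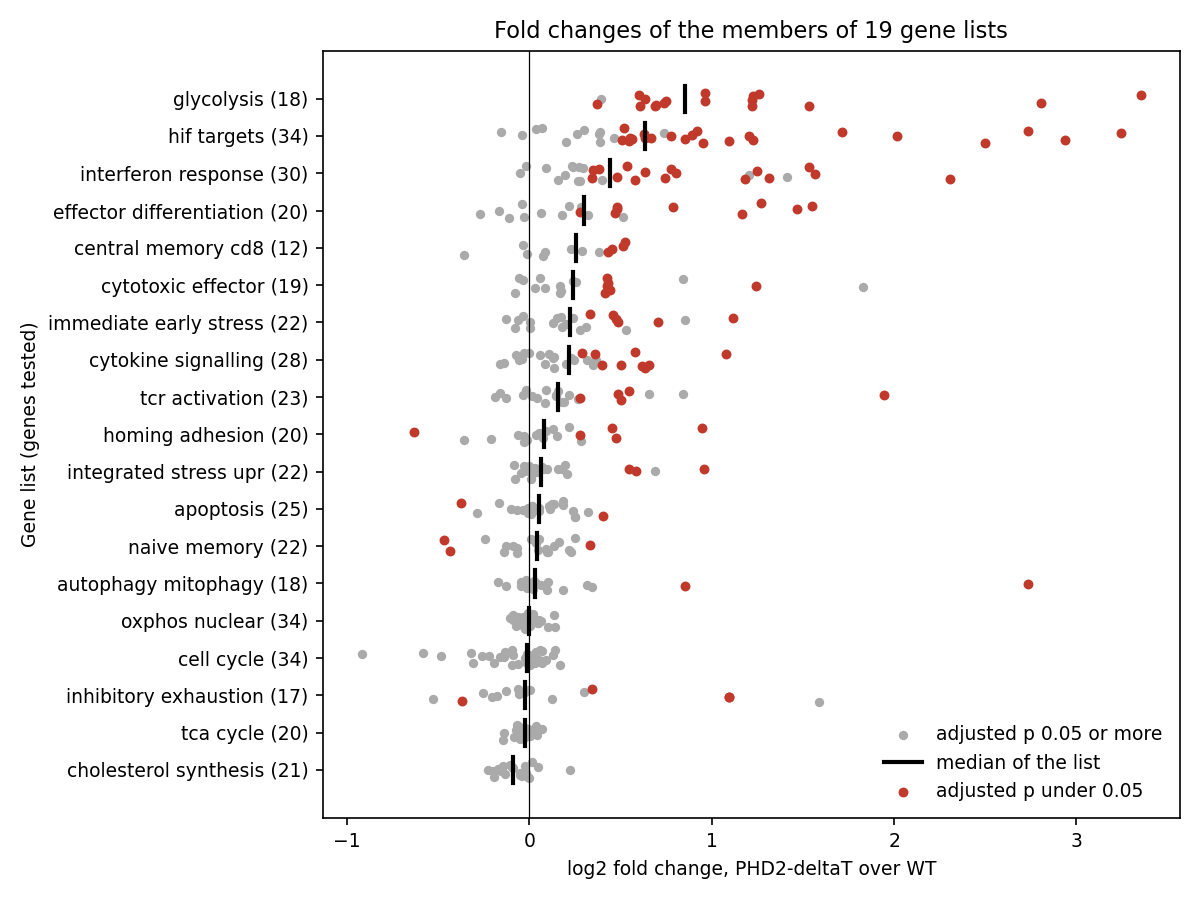
Log2 fold changes (PHD2-deltaT over WT) of the tested members of 19 gene lists, 1 dot per gene, red where the adjusted p is under 0.05, with a black bar at each list's median. Glycolysis and HIF target genes have the highest medians, 0.85 and 0.63, and tricarboxylic acid cycle genes sit near 0.

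Markers of the sorted and of other cell types were read in the same fit. Every gene in the deposited table had at least 1 inferred read in every library, so markers without reads in a library may be missing. Tested were 8 of 18 listed B cell, 8 of 12 dendritic, 6 of 12 natural killer and 6 of 20 myeloid markers. The markers left out cannot speak for or against other cells. Of 15 T cell markers, 2 were higher, Cd2 (0.39) and Cd247 (0.29), 2 also when adjusted over the list alone (camera adjusted p = 0.509). Both were lost without WT replicate 2 (adjusted p = 0.093 and 0.43), Cd247 also without PHD2-deltaT replicate 1 (0.082) or 3 (0.081). Cd247 shares 60.3% of its exon bases with other genes. Of 8 B cell markers, 3 were higher, 3 also when adjusted over the list alone: H2-Ab1 (2.87), Cd74 (0.61) and Igkc (from 4.47 ± 3.48 to 42.4 ± 21.1). Cd79b (0.34) did not pass. The list's camera adjusted p was 0.000135, and the adjusted p was 0.203 with an estimated correlation. Of 8 dendritic cell markers, 5 were higher (5 adjusted over the list alone), Irf8, Batf3, Zbtb46 (1.15), Itgax (1.06) and Bst2 (0.35), with a camera adjusted p of 7.96e-05 and an adjusted p of 0.203 with an estimated correlation. Of these, Batf3, Itgax and Bst2 were lost without WT replicate 1 (adjusted p = 0.21, 0.058 and 0.10), where 2 of the list were called. Of 6 natural killer markers, 1 passed (1 adjusted over the list alone), Eomes (0.51), with a camera adjusted p of 0.0131 and an adjusted p of 0.203 with an estimated correlation. This list's camera call was lost without WT replicate 2 (median 0.34 against 0.51, adjusted p = 0.11) and with a minimum of 50 (0.28, adjusted p = 0.062). Of 9 CD4 and regulatory T cell markers, 1 was lower, Nrp1, and 3 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.538). Among plasma cell (4 tested), myeloid (6), stromal and endothelial (3), erythroid (1) and platelet (1) markers, 0 passed, and no neutrophil marker was tested. Adjusted over the list alone, 1 myeloid marker was higher and 1 stromal or endothelial marker lower. The camera adjusted p of the plasma cell, myeloid, and stromal and endothelial lists were 0.538, 0.191 and 0.538. Examples were Derl3 (0.54), Cebpb (0.82), Eng (-0.41), Car2 (-0.24) and Itgb3 (0.10). Eng passed without PHD2-deltaT replicate 1 (-0.53, adjusted p = 0.039), and ranged from -0.61 to -0.21 over the fits without 1 library. Of 34 ribosomal protein genes, 0 passed (median -0.06, camera adjusted p = 0.0386; adjusted p = 0.771 with an estimated correlation), with Rps2 at -0.16. The ribosomal median turned to 0.02 without WT replicate 1 and 0.00 without PHD2-deltaT replicate 1, where the test pointed upward and did not pass (adjusted p = 0.61 and 0.94). It was -0.14 without WT replicate 2, and the call was also lost under TMM (adjusted p = 0.085) and quantile scaling (0.051). Among 3 replication-dependent histone genes and 4 sex chromosome genes, 0 passed (camera adjusted p = 0.954 and 0.0541), though the sex chromosome list passed camera without PHD2-deltaT replicate 1 (adjusted p = 0.0076). Counted with the PHD and HIF pathway and mitochondrially encoded genes above, these other gene groups held 20 called genes, 12 without WT replicate 2 and 5 without the trend. The 5 were Egln1, Egln3, Nrp1, H2-Ab1 and Itgax.

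The authors' deposited table was compared with the fit. It listed 448 genes with an FDR under 0.05, of which 418 were also called here, each in the same direction. Sizes differed: over the selected genes described below, the median ratio of the authors' log2 fold change to the one here was 0.788. For Mgarp, Egln3 and Itga7 the authors' table gave -0.37, -1.36 and -0.76 (WT over PHD2-deltaT), against 4.27, 3.25 and 3.16 here (PHD2-deltaT over WT). Another 30 were called only in the authors' deposited table and 43 only here. The authors' deposited table also marked a selection of 132 genes with a negative and 19 with a positive fold change. The sign there was WT over PHD2-deltaT. All 132 were higher and all 19 lower in the libraries labelled PHD2-deltaT, and all 151 passed. The selection was made on these libraries and is not independent evidence.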

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

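The fits with limma-voom on inferred reads and with corrections for merged exon length and GC content were chosen after seeing the data. Of 92 called genes named in the text, 61 were called in every fit that left out 1 library, and none changed direction in any setting run. Egln1 stayed higher and past the threshold in all settings run. Without 1 library the calls ranged from 244 to 523 (higher 209 to 362, lower 35 to 161), and the other gene groups from 12 to 21. The fits without a WT library leave a lone WT sample, assumed to vary like the others. Limma without the trend called 96 genes (76 higher, 20 lower) and lost 59 of the 92 named calls. It called 74 of the authors' selection and 5 in the other gene groups. Requiring a 2-fold change left 100 (89 higher, 11 lower), and an adjusted p under 0.1 gave 713 (242 lower). Of 13 biological lists past the threshold, 1 passed with an estimated correlation and 6 with fry. The 6 were glycolysis (fry adjusted p = 0.00299), HIF targets, effector differentiation, interferon response, cytokine signalling, and autophagy and mitophagy (each 0.0397). Some lists share members, so their results are not independent of each other. The other scalings, pseudocounts, filters, robust eBayes, array weights, limma-voom and corrections gave 433 to 515 calls. The cause of these shifts was not tested, beyond fewer libraries or a stricter threshold.

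Apart from the ribosomal protein list, the sign turned only for results that were not called. That list had passed, and its median ranged from -0.144 to 0.0236 without 1 library. Without 1 library, Hif1a ranged from -0.0929 to 0.153, Arnt from -0.0506 to 0.171 and Itgb3 from -0.0593 to 0.189. List medians then ranged from -0.0407 to 0.0242 for oxidative phosphorylation, -0.0127 to 0.0890 for naive and memory, -0.0827 to 0.0280 for inhibitory and -0.0443 to 0.0133 for cell cycle genes. The direction of the test turned without 1 library for T cell markers (median -0.100 to 0.0287), CD4 markers (0.166 to 0.227) and histone genes (-0.116 to 0.355). It also turned with a minimum of 50 for inhibitory genes (median -0.0399) and CD4 markers (0.159), and with fry for CD4 markers (0.218). For histone genes it turned with the length, GC and joint corrections (0.153, 0.162 and 0.132). The cause was not tested. No paired analysis was possible: the labels link no WT library to a PHD2-deltaT one, and replicate numbers here follow only their order. The planned edgeR and DESeq2 fits were not run, since the values were rounded up after scaling. At these depths and group sizes, with the same dispersion for every gene, 72.4% of simulated 1.5-fold changes were recovered, and depth was not varied.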

Other observations

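All tests in this part except that of the glycogen genes were chosen after the result they bear on was seen, and the ERK list held 3 genes whose values had been seen. Called genes clustered around the targeted locus. Within 5 Mb of Egln1 on chromosome 8, 14 of 75 other tested genes passed the threshold (18.7%), against 3.88% of genes elsewhere (Fisher's exact p = 1.21e-06; genes are not independent replicates). Within 10 Mb the share was 15.1% (Fisher's exact p = 1.66e-05), and within 20 Mb 7.94% against 3.91% (p = 0.0123). Calls went both ways. Cdh15 (3.78), Abcb10 (0.94), Irf8 (0.54) and Ttc13 (0.41) were higher, and Tubb3 (-2.27), Nrp1 (-1.62), Fanca (-1.30), Klhdc4 (-1.19) and Def8 (-0.42) were lower. Without WT replicate 2 Def8 (adjusted p = 0.10) and Ttc13 (0.15) were not called, and without WT replicate 1 Def8 was not (0.10). Limma without the trend did not call Irf8 (adjusted p = 0.096), Tubb3 (0.083), Def8 (0.19) or Ttc13 (0.21). Of 11234 windows reaching 20 Mb around genes over 40 Mb away, 71 held as many lower calls as the 7 around Egln1. Such windows overlap and are not separate loci. The lower calls had prompted the pattern, so this count only describes it.

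DNA of another mouse strain kept around the targeted Egln1 allele is a candidate explanation that no value here decides. A first test at 20 Mb on all calls (p = 0.0123 by Fisher's exact test) held the lower calls that had prompted it, so it restated the pattern and supports no cause. The test was then moved to the higher calls at the same distance, with 4.23% near Egln1 against 2.94% elsewhere (Fisher's exact p = 0.276). At 5 and 10 Mb the exact p of the higher calls were 0.00164 and 0.00627. The labels give no strain. A local effect of the altered allele on its neighbours, or regulation of these genes by HIF, would also place calls there and was not tested. Until strain is known, changes of Nrp1, Klhdc4, Fanca, Irf8 and Egln1 itself may belong to the locus and not to loss of PHD2.

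The rise of Egln1 in the libraries labelled PHD2-deltaT was weighed against an exchange of genotype labels. Loss of PHD2 should raise HIF targets, and these had a median log2 fold change of 0.63 (standard error 0.10) in the libraries labelled PHD2-deltaT, which argues against an exchange. Egln1 may instead have risen with other HIF targets, among which its change stood at percentile 72.7 of those called. Reads over deleted exons were not analysed here, so how much of the transcript was intact stays open.

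Genes with many exon bases were frequent among the lower calls. The length used was the exon bases of a gene merged over its isoforms, and transcript length itself was not measured. Of 116 lower calls with a length, 59 lay in the longest 20% of genes (50.9%), against 7.60% of the higher calls. Across genes the change had a Spearman correlation of 0.239 with GC content and -0.172 with length. After a GC correction 54 of the 59 were still called, so a GC trend alone is unlikely for most of them. After a joint length and GC correction 35 of the 59 were called. After a length correction 31 of the 59 were called, and their median log2 fold change went from -0.46 to -0.39. Some calls ended as the changes shrank, and a length trend, as RNA integrity can give, cannot be told apart from a change of long genes for these.

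Some B cell genes were higher, in cells sorted as CD8 T cells. H2-Ab1 gained 105 ± 20.8 normalized counts (SE), while H2-Aa (4.12) and H2-Eb1 (8.57) together averaged 6.06% of that gain. Antigen-presenting cells make all 3 at high levels, which argues against such cells as the source of H2-Ab1. Cd74, which they also make, gained 176 ± 23.4 (SE), and 5 of 8 dendritic cell markers were higher, so the source of those rises stays open. Among these markers, Irf8 and Batf3 are also on the T cell receptor activation list and Bst2 is on the interferon response list. Their rise therefore does not single out dendritic cells. For Igkc the source stays open: Cd79b, Ighd and Ighm had a median log2 fold change of 0.21 (standard error 0.22). In normalized counts Igkc gained 38.0 ± 12.4 (SE) and Cd79b 39.3 ± 12.5 (SE), so B cells remain possible. Gains of Ighd and Ighm on that scale were not computed.

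A pair of hypotheses drawn from named genes gave no clear answer. Spry2 (-0.86) and Dusp4 (-0.62) were lower, which might reflect lower ERK signalling. The 13 other ERK feedback and response genes did not pass (limma's camera, adjusted p = 0.237 over both lists), with Spry1 lower (-0.32) and Dusp5 higher (0.48). Without WT replicate 2 neither was called (adjusted p = 0.14 and 0.082), and Spry1 was called in 1 of the 5 fits without 1 library. Glycogen genes prompted by Gys1, Gbe1 and Ppp1r3b might have risen as a group. The 11 others did not pass (limma's camera, 0.194 unadjusted, adjusted p = 0.237), although Pgm2 was called (1.06).

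With 5 libraries there are 10 splits into 3 and 2, too few for a share under 0.05. The real split, 1 of the 10, called 461 genes and the highest of the others called 1. Every other split mixes the genotypes in at least 1 group, so a difference between genotypes adds to its spread and lowers its calls. The contrast also cannot separate genotype from anything else shared by a group's libraries.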
